A study of Oncorhynchus mykiss with 6 samples.

How the data were processed

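Ribosome footprints of rainbow trout liver were measured in 6 libraries, 3 control and 3 heat stress. Per the labels' protocols, footprints were purified with an RNA clean-up kit and made into libraries with a small RNA kit, and the molecule is labelled nuclear RNA. Bowtie2 and edgeR are named in the submitters' processing notes, with no role or version. The genome build, the annotation and the read counter are not given in the sources used here, and neither are adapter trimming, rRNA removal or footprint lengths.

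The authors deposited 1 table with whole-number footprint counts and FPKM per library, mean FPKM per group, a log2 fold change, a p-value and an FDR per gene. Per the file headers, the count columns carry the same library names as the sample titles. The authors' deposited log2 fold change equals log2 of the ratio of the group mean FPKM, and a mean of 0 was replaced by a small number, so it is no measured fold change for a gene at 0 in a group. The table is fixed-width text with 8 characters per cell, so gene identifiers, long symbols and descriptions are cut short. The 1213 genes share 4 distinct cut identifiers, so neither identifiers nor coordinates can be given. A symbol was present for 1165 genes and missing for 48, and 73 symbols of 8 characters may be cut. In 12 p-values a digit of the exponent was lost. A further 411 lines hold annotation text that overflowed its cell and were not used.

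Only genes with the authors' FDR under 0.05 and at least a 2-fold change were in the table. Full library totals were therefore not used. A count divided by its FPKM is proportional to library depth times gene length, so the ratio between 2 libraries gave their relative depth, over 94 genes with at least 200 footprints and 10 FPKM, with an SD of at most 1.2%. These depths served as library sizes. The number of genes the authors tested, estimated from FDR, rank and p-value, was about 29300, and p-values were adjusted by Benjamini-Hochberg over that number. The authors' FDR implies about 1580 genes passing 0.05, of which about 370 changed less than 2-fold and were not analysed here.

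The design fixed before the data were examined named a quasi-likelihood count test with TMM scaling as the main test. It was replaced. TMM takes most genes as unchanged, which a table of selected genes contradicts, and the unit of the count columns could be entered for the unit check only as unspecified, because the check cannot read cells that touch. The main test was limma-voom (limma 3.58.1, R 4.3.3) without TMM, and the count under TMM stands beside it. Genes with at least 10 depth-scaled footprints in 3 libraries and 15 in all were tested, which left 1152 and excluded 61. A fold against a group at 0 is given as a lower bound against 3 footprints over the group, which covers counting error only. Gene lists were tested with camera (preset correlation 0.01, estimated correlation as an alternative) and fry, on lists with at least 3 tested members. Camera compares a list with the other listed genes, of which most rose, not with the genome, so "below" is relative to them. No enrichment against a background of all genes was possible with a selected table. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used for tables, exact tests and figures.

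Lists and markers were fixed before the data were examined and matched by the start of a symbol or description, so a few members matched by prefix alone. Descriptions are cut to 8 characters, so description patterns longer than that could not match. The lists therefore rest mostly on symbols and can miss members. Named genes were chosen by a rule also fixed before the data were examined. It took the 10 largest rises and 10 largest falls among genes past the test with a symbol, above the median expression and without overlap between groups. It also took up to 4 genes with the smallest p from each list with at least 3 called members, and 8 fixed stress genes. Of several entries with one symbol, that with the smallest p was named. The genes LIPE, FGA, eif4ebp3, eef1akmt, ppox, alas1 and grp94, and the c3 entry more abundant in control, fall outside this rule. They were chosen after their values were seen. The text names a part of the genes this gave, and some are not reported here.

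The test was tried on simulated counts for the 1213 genes, of which 1162 were tested and 200 changed. It recovered 59.4% of changes of log2 size 1 and 99% of size 2, with 0 calls among unchanged genes. Adjustment over about 29300 genes, as for the data, made calls among unchanged genes unlikely in advance. The simulation used known library sizes, as many rises as falls and 1 dispersion, so it does not bear on the scaling or the selection. No pair of replicates agreed within sampling noise (chi-square per degree of freedom 15.7 to 34.3), so no library was a copy of another. Trout genomes hold many near-identical gene copies. Entries with identical counts in all 6 libraries formed 9 groups, and 8 entries were set aside as copies in 1 alternative. How reads matching several copies were counted is not given in the sources used here, so values of genes with several entries are uncertain. Alternatives covered scaling, low-count filters, thresholds, FPKM in place of counts, a replicate block and each library left out.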

Results

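Ribosome footprints, the short mRNA pieces that ribosomes protect from nuclease, were sequenced from the liver of rainbow trout (Oncorhynchus mykiss), a cold-water salmonid. The 6 libraries form 2 groups of 3: a control group, and a group kept at 24 °C for 8 h, called heat stress here. The sample descriptions and the series' design text give 18 °C for the control group, whereas the treatment protocol gives 20 °C. Nothing in the labels says whether the 3 libraries of a group came from separate fish, so p-values measure the spread between these libraries, which may be partly technical. The deposited table lists 1213 genes, each with the authors' FDR under 0.05 and at least a 2-fold change. Genes outside that selection were not analysed here. The listed genes held 503370, 420513 and 362308 footprints in control replicates 1, 2 and 3. They held 679067, 438701 and 863769 in heat stress replicates 1, 2 and 3. The depth of each library relative to control replicate 1, recovered from counts and FPKM, was 76.4% and 65.5% in control replicates 2 and 3. It was 72.2%, 41.4% and 82.0% in heat stress replicates 1, 2 and 3. Footprints depend on mRNA amount as well as on translation, and no matched RNA measurement was used here.

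The comparison asked which genes' footprints differed between heat stress and control liver. Heat shock chaperones were among the genes with the largest rises. The inducible Hsp70 gene hspa1b went from 0.543 ± 0.480 FPKM in control to 1261 ± 333 FPKM in heat stress (SD, n = 3 per group). The Hsp90-alpha gene hsp90a.1 went from 6.27 ± 1.19 to 1524 ± 225 FPKM, and the Hsp40 family gene dnaja from 8.10 ± 1.67 to 1252 ± 330 FPKM. The plasma protein genes apoa-i-1, rbp4 and alb1, and the lipid synthesis genes FASN and hmgcra, were lower in heat stress. The authors' deposited table gives 924 genes as higher and 289 as lower in heat stress.

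Tested again with limma-voom on the counts, 1008 of 1152 genes with enough footprints passed an adjusted p of 0.05, of which 821 were higher and 187 lower in heat stress. Because every gene had already been selected on these same libraries, this count does not estimate how much of the genome changed, and fold changes of selected genes tend to be overestimates. At an unadjusted p under 0.05, 1151 of the 1152 passed, so the counts below that are adjusted over the list alone were fixed by the selection: every tested member passed in each list. Groups did not overlap in 1197 of the 1213 listed genes, where chance alone gives 10%, but the selection favours such genes. The balance of rises and falls depended on the scale. With TMM factors taken over the listed genes, 90 genes were higher and 266 lower, 25.3% higher in place of 81.4%, and the median log2 fold change shifted by -1.48. Median-of-ratios factors gave 88 higher and 266 lower, with a shift of -1.54. Library sizes from the listed footprints gave 207 higher and 262 lower, with a shift of -0.93. Without the 10 most abundant genes these sizes gave 150 higher and 264 lower, with a shift of -1.19. TMM and median of ratios take most listed genes as unchanged, although each was selected as changed, and the other scalings take their summed footprints as equal between libraries. The sign of the log2 fold change turned in 220 genes under TMM, 254 under median of ratios, 79 without the 10 most abundant genes and 0 with all listed footprints, and 0 of these genes then passed the test. The 90 genes higher and the 187 genes lower under both TMM and recovered depth kept their calls. Leaving out control replicate 1, control replicate 3 or heat stress replicate 3 reduced the 1008 genes to 534, 649 and 625.

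Heat shock proteins and co-chaperones rose as a group. All 71 listed members were higher in the authors' deposited table, and 69 of 70 tested members rose by limma-voom, with 70 passing when adjusted over the list alone. With each library left out in turn, 55 of the 69 kept their calls throughout. Up to 8 members had a log2 fold change below 0 under the scalings over the listed genes, none past the test. The list's median log2 fold change was 3.637 by recovered depth and 2.148 under TMM. How many of the 69 calls held under TMM is not reported here. The log2 fold change was 11.29 ± 0.57 (SE) for hspa1b (limma-voom adjusted p = 2.76e-06) and 7.93 ± 0.24 for hsp90a.1 (limma-voom adjusted p = 1.16e-07), 1 of 3 entries with that symbol. Hspa4, a relative of Hsp70 with 3 entries, rose from 19.3 ± 5.30 to 890 ± 150 FPKM (SD, n = 3) and dnajb1b, an Hsp40 co-chaperone, from 2.83 ± 0.888 to 205 ± 25.6 FPKM. The small heat shock protein gene hsp30 had no footprint in any control library. Against a floor of 3 footprints over the control group it was at least 434-fold higher, at 119 ± 51.1 FPKM in heat stress, and it is 1 of 5 entries. The constitutive Hsc70 gene hspa8b rose from 73.3 ± 37.4 to 511 ± 55.5 FPKM. The Hsp90-beta gene hsp90ab1 was 204 ± 56.5 FPKM in control and 509 ± 42.5 in heat stress, with log2 fold changes of 1.33 by recovered depth, -0.16 by TMM and -0.22 by median of ratios. Its limma-voom adjusted p was 0.0129, and 0.078 without heat stress replicate 2. Hsf1, the transcription factor of the heat shock response, was not among the listed genes. The list stood above the other listed genes by camera with a preset correlation of 0.01 (adjusted p = 3.04e-07), but not with an estimated correlation (adjusted p = 0.234 with an estimated correlation).

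**Figure D1:**
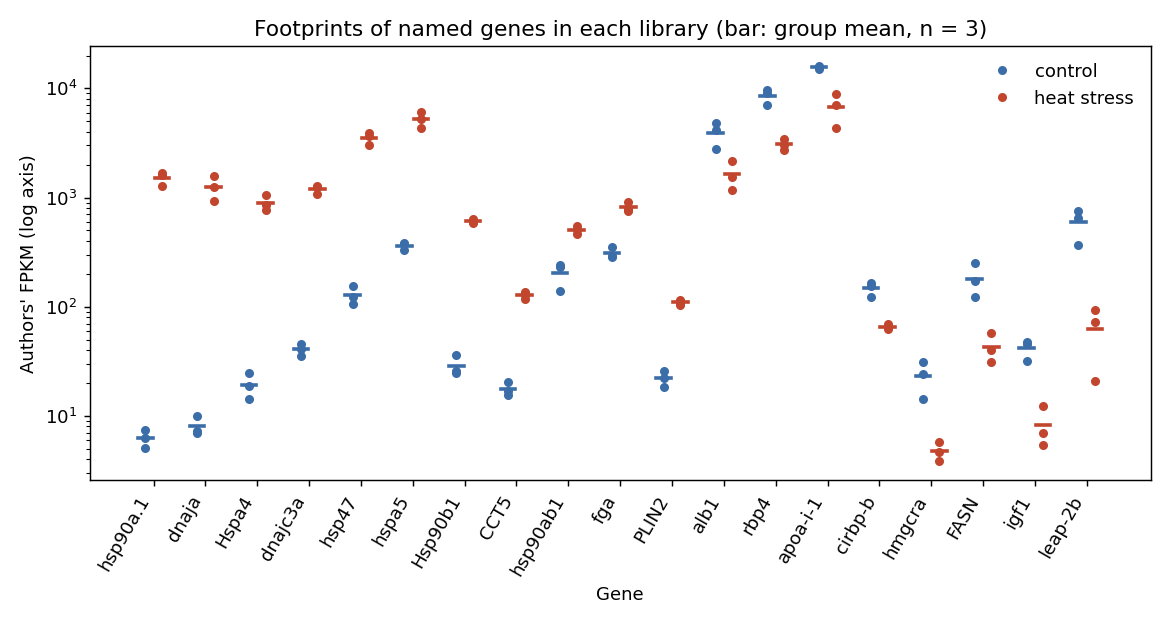
Each point is the authors' FPKM of 1 gene in 1 library on a log axis, blue for the 3 control and red for the 3 heat stress libraries, and each bar is the group mean. The gene hsp90a.1 lies between 5.07 and 7.45 FPKM in control and between 1267 and 1683 FPKM in heat stress; under TMM over the listed genes hsp90ab1 and fga have log2 fold changes below 0, neither past the test.

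Genes of protein folding in the endoplasmic reticulum rose together. All 54 listed members were higher and all 54 passed by limma-voom, and 54 passed when adjusted over the list alone. Up to 12 had a log2 fold change below 0 under median of ratios, none past the test, and 0 with listed footprints. With each library left out in turn, 41 kept their calls throughout. The list's median log2 fold change was 2.090 by recovered depth and 0.616 under TMM. How many of the 54 calls held under TMM is not reported here. The list shares members with the heat shock list, among them hspa5, Hsp90b1 and dnajc3a, so the lists are not separate sets of genes. The ER Hsp70 gene hspa5 (BiP) rose from 362 ± 28.9 to 5219 ± 844 FPKM (SD, n = 3), and the ER Hsp90 gene Hsp90b1 from 28.8 ± 6.04 to 604 ± 27.6 FPKM. A more abundant entry, grp94, another symbol for the ER Hsp90, had a group mean of 730 FPKM in control and 2961 FPKM in heat stress. The ER chaperone gene hyou1 rose from 43.4 ± 6.01 to 627 ± 66.7 FPKM, and dnajc3a, an ER co-chaperone, from 40.8 ± 5.04 to 1196 ± 107 FPKM. The symbols hspa5, Hsp90b1 and hyou1 each had 2 entries. The collagen chaperone gene hsp47 rose from 128 ± 25.3 to 3527 ± 438 FPKM. All 13 listed entries for the cytosolic chaperonin TRiC, with 8 distinct symbols, passed by limma-voom and rose, 11 of them with every library left out in turn. All 13 passed when adjusted over the list alone, with 2 below 0 under TMM, neither past the test. The median log2 fold change of the TRiC list was 2.227 by recovered depth and 0.728 under TMM. How many of the 13 calls held under TMM is not reported here. Among the TRiC entries CCT5 rose from 17.6 ± 2.57 to 127 ± 8.98 FPKM and cct3 from 12.5 ± 3.72 to 83.4 ± 2.87 FPKM, each with 2 entries. Camera placed ER folding (adjusted p = 4.73e-05) and TRiC (adjusted p = 0.0253) above the other listed genes. Both calls were lost with an estimated correlation: adjusted p = 0.567 with an estimated correlation for ER folding, and adjusted p = 0.739 with an estimated correlation for TRiC. The TRiC call was also lost without heat stress replicate 1 (camera adjusted p = 0.058) and among genes with at least 10 FPKM in 3 libraries (camera adjusted p = 0.0807).

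Genes of cholesterol and bile acid synthesis were lower in heat stress. Of 9 listed members, 7 fell, 1 rose and 1 did not pass by limma-voom, and 9 passed when adjusted over the list alone. The gene of HMG-CoA reductase, the rate-limiting enzyme of cholesterol synthesis, hmgcra, fell from 23.3 ± 8.42 to 4.77 ± 0.924 FPKM (SD, n = 3). SQLE, the squalene epoxidase gene, fell from 11.9 ± 4.21 to 2.21 ± 1.48 FPKM, and the squalene synthase gene fdft1 from 4.44 ± 1.09 to 0.530 ± 0.344 FPKM. SQLE and fdft1 lost their calls without heat stress replicate 2 or 3, with limma-voom adjusted p up to 0.0719 and 0.0812. Of the list's 8 calls, 5 held without control replicate 1, 4 without control replicate 2 or 3, and 1, that of hmgcra, without heat stress replicate 2 or 3. Camera placed the list below the other listed genes (adjusted p = 4.73e-05), which it did not with an estimated correlation (adjusted p = 0.243 with an estimated correlation), nor among genes with at least 10 FPKM in 3 libraries (camera adjusted p = 0.101). Of 21 listed genes of fatty acid and triglyceride metabolism, 9 rose, 8 fell and 4 did not pass, and 21 passed when adjusted over the list alone. Of its 17 calls, 11 held without control replicate 3 or heat stress replicate 2, and 10 without heat stress replicate 3. FASN, the fatty acid synthase gene, fell from 181 ± 64.8 to 42.9 ± 13.4 FPKM in 1 of 2 entries, and the other did not pass. PLIN2, which coats lipid droplets and has 2 entries, rose from 22.0 ± 3.73 to 109 ± 4.76 FPKM, and the hormone-sensitive lipase gene lipe1 rose from 2.62 ± 1.10 to 20.1 ± 1.56 FPKM, whereas LIPE, the symbol of the same lipase, fell from 3.29 ± 0.298 to 0.863 ± 0.244 FPKM. The LIPE call was lost without control replicate 3, heat stress replicate 1 or heat stress replicate 3 (limma-voom adjusted p up to 0.0742). This list lay below the other listed genes by camera (adjusted p = 0.00503; adjusted p = 0.234 with an estimated correlation). Fry, which tests against 0 change, gave adjusted p = 0.269. By recovered depth the list's median log2 fold change was -1.02 and its mean 0.04, so on that scale the mean did not share the sign of the camera test. Under TMM over the listed genes the median was -2.51.

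All 7 entries listed as secreted plasma proteins, with 5 distinct symbols, fell by limma-voom, and 7 passed when adjusted over the list alone. Of these calls, 4 held without control replicate 1 or 3, 2 without control replicate 2, and 3 without heat stress replicate 2 or 3. The apolipoprotein A-I gene apoa-i-1, the most abundant listed gene, fell from 15659 ± 497 to 6764 ± 2341 FPKM (SD, n = 3). The list also holds 2 entries of ZP2, an egg coat protein gene. The retinol carrier gene rbp4, 1 of 2 entries, fell from 8598 ± 1350 to 3070 ± 340 FPKM, and the albumin gene alb1 from 3901 ± 1041 to 1631 ± 510 FPKM. The apoa-i-1 call held without heat stress replicate 1 alone, with limma-voom adjusted p up to 0.102 without the others in turn. The alb1 call was lost without control replicates 2 or 3, or heat stress replicates 2 or 3, with limma-voom adjusted p up to 0.190. Camera gave an adjusted p of 2.56e-05 for the list, below the other listed genes (adjusted p = 0.154 with an estimated correlation). The 10 most abundant listed genes took 44.2% ± 0.857 of listed footprints in control and 32.9% ± 1.87 in heat stress (SD, n = 3; exact permutation test, two-sided, p = 0.1, the smallest that 3 against 3 libraries allow). These 10 include genes that rose, such as hspa5 and hsp47. Listed footprints per recovered depth were 1.9-fold higher in heat stress, so a lower share of them does not mean fewer footprints of these 10 genes. The planned share of all footprints was not computed, because full library totals were not used. The 50 most abundant took 72.3% in control and 68.4% in heat stress (exact permutation test p = 0.1), and the 100 most abundant 81.0% and 79.0% (exact permutation test p = 0.2).

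Of 13 listed genes of cytochrome P450 and xenobiotic metabolism, 5 fell, 3 rose, 3 did not pass and 2 were not tested by limma-voom, and 11 passed when adjusted over the list alone. Of the 8 calls 5 held without control replicate 1. NAT1, an arylamine acetyltransferase gene, fell from 24.2 ± 1.41 to 7.25 ± 0.566 FPKM (SD, n = 3). Ugt2a2 was 153 ± 6.14 and 322 ± 18.0 FPKM, with a log2 fold change of 1.07 by recovered depth and -0.42 by TMM. Its call was lost without control replicate 3 (limma-voom adjusted p = 0.0587). Camera placed the list below the other listed genes (adjusted p = 0.000848; adjusted p = 0.154 with an estimated correlation). Of 8 listed cell cycle and DNA replication genes, 6 fell, 1 did not pass and 1 was not tested, and 7 passed when adjusted over the list alone. Of these 6 calls, 2 held without control replicate 1 or heat stress replicate 2, and 3 without each other library. The replicative helicase gene mcm3 fell from 5.32 ± 1.46 to 0.687 ± 0.119 FPKM. Camera gave adjusted p = 3.21e-05 for this list (adjusted p = 0.154 with an estimated correlation), and too few members had 10 FPKM in 3 libraries for a test. Of 11 listed circadian clock genes, 5 fell, 2 rose, 2 did not pass and 2 were not tested, and 9 passed when adjusted over the list alone. The transcriptional repressor gene bhlhe40, 1 of 3 entries, fell from 23.6 ± 5.38 to 3.75 ± 0.577 FPKM, and HLF, 1 of 2 entries, had a log2 fold change of -3.09 ± 0.40 (SE). This HLF entry had the same footprint counts as the entry dbpb in control replicate 3 and every heat stress library, so the entries may share reads. NFIL3 rose from 2.07 ± 0.550 to 8.81 ± 1.77 FPKM and TEF from 0.800 ± 0.135 to 21.9 ± 13.2 FPKM. The TEF call was lost without control replicate 1 (limma-voom adjusted p = 0.0532). Camera placed the clock list below the other listed genes (adjusted p = 0.000389; adjusted p = 0.234 with an estimated correlation).

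**Figure D2:**
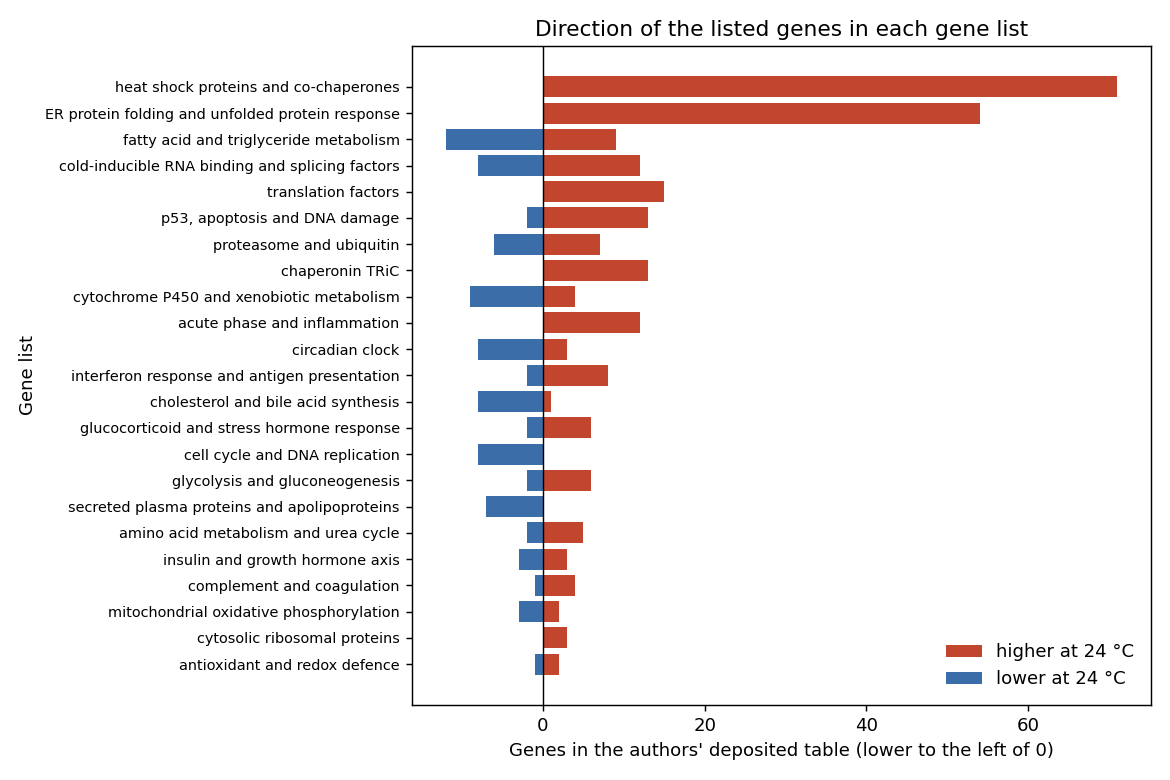
Bars count the genes of each fixed list that the authors' deposited table gives as higher (red, right) or lower (blue, left) at 24 °C. The heat shock list holds 71 higher and 0 lower genes, and the plasma protein list 0 higher and 7 lower; under TMM over the listed genes 8 heat shock genes have log2 fold changes below 0, none past the test.

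The other lists did not stand apart from the other listed genes by camera. All 15 entries matched as translation factors were higher, 13 rose by limma-voom, and 15 passed when adjusted over the list alone (camera adjusted p = 0.176), with 4 below 0 under TMM, none past the test. Among the entries are eif2ak3, a kinase gene, eif4ebp3, a translation repressor gene, and eef1akmt, a methyltransferase gene, which matched by the start of their symbols. Of the 13 calls 6 held without control replicate 1, and 8 without control replicate 2 or heat stress replicate 3. EIF4G2, 1 of 2 entries, rose from 4.26 ± 0.830 to 20.2 ± 4.66 FPKM (SD, n = 3). Of 13 proteasome and ubiquitin genes 7 rose and 2 fell (camera adjusted p = 0.784), with 11 passing when adjusted over the list alone. Under TMM the sign turned in 2 members, neither past the test, and the list's median log2 fold change was -0.161 in place of 1.315. VCP, an ATPase that extracts ubiquitinated proteins, rose from 68.4 ± 11.9 to 222 ± 30.9 FPKM. All 12 entries matched as acute phase and inflammation genes were higher, 11 rose, and 12 passed when adjusted over the list alone (camera adjusted p = 0.229). However, up to 6 were below 0 under the scalings over the listed genes, none past the test. Their 8 distinct symbols are NFKBIA, NFKBIZ, NFKBIE, Nfkb2, cebpb, tlr5, Tnfrsf14 and TNFRSF6B. These are genes of regulators and receptors, and none is an acute phase protein gene. Among them NFKBIZ rose from 4.33 ± 1.52 to 22.9 ± 4.55 FPKM. Of these 11 calls, 2 held without control replicate 1, 6 without control replicate 3 and 7 without heat stress replicate 3. The list missed leap-2b, an antimicrobial peptide gene, and pxn1, a pentraxin gene, because of their symbol spelling and cut descriptions. Both fell by limma-voom, leap-2b from 593 ± 203 to 62.06 ± 37.05 FPKM and pxn1 from 37.9 ± 18.9 to 7.55 ± 4.52 FPKM. The pxn1 call was lost in 4 of the fits with 1 library left out (limma-voom adjusted p up to 0.139). Of 10 interferon response genes 6 rose and 2 fell, including GBP1, which rose from 15.6 ± 4.63 to 100.1 ± 13.5 FPKM, with 9 passing when adjusted over the list alone (camera adjusted p = 0.788). Without control replicate 1, 5 of these 8 calls held. Of 15 genes of p53, apoptosis and DNA damage 8 rose and 2 fell, with 12 passing when adjusted over the list alone (camera adjusted p = 0.786). Of these 10 calls, 6 held without control replicate 1, and 5 without control replicate 2, control replicate 3 or heat stress replicate 3. The AP-1 gene JUN, 1 of 2 entries, rose from 7.28 ± 2.29 to 62.3 ± 10.9 FPKM, and bag3, a co-chaperone that also falls in this list, from 0.553 ± 0.347 to 24.6 ± 2.80 FPKM.

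Among 20 listed genes of cold-inducible RNA binding and splicing, 11 rose and 6 fell, and 19 passed when adjusted over the list alone (camera adjusted p = 0.23). The sign turned in 4 members under median of ratios and 3 under TMM, none past the test. The list's median log2 fold change was 1.468 by recovered depth and -0.007 under TMM. Of the 17 calls, 10 held without control replicate 1 and 11 without heat stress replicate 3. The cold-inducible RNA-binding gene cirbp-b was 148 ± 21.9 FPKM in control and 65.8 ± 3.97 in heat stress (SD, n = 3), lower by limma-voom (adjusted p = 0.00968), with adjusted p up to 0.0556 without control replicate 1 or heat stress replicate 3. Of 8 glycolysis and gluconeogenesis genes 6 rose and 2 fell, and 8 passed when adjusted over the list alone (camera adjusted p = 0.786). Of these 8 calls, 1 held without control replicate 1, 8 without heat stress replicate 1 and 5 without each other library. Of 7 amino acid metabolism genes 4 rose and 2 fell, with 7 passing when adjusted over the list alone (camera adjusted p = 0.786). Of these 6 calls, 2 held without control replicate 2, control replicate 3 or heat stress replicate 3, and 3 without heat stress replicate 2. The proline dehydrogenase gene Prodh rose from 18.5 ± 0.538 to 93.8 ± 29.8 FPKM. Of 5 complement and coagulation entries 4 rose and 0 fell, with 5 passing when adjusted over the list alone (camera adjusted p = 0.788), and 3 of the 4, fga, FGA and c7b, were below 0 under TMM, none past the test. The entries fga and FGA had identical counts in all 6 libraries, so they are 1 measurement. In the authors' deposited table the 2 c3 entries moved opposite ways. The entry less abundant in control rose by limma-voom, with group means of 214 FPKM in control and 629 FPKM in heat stress. The entry more abundant in control had group means of 486 FPKM in control and 226 FPKM in heat stress. It did not pass (limma-voom adjusted p = 0.112). The c7b call held only without heat stress replicate 1, with limma-voom adjusted p up to 0.156 without the others in turn. Of 8 glucocorticoid response genes 3 rose, with 8 passing when adjusted over the list alone (camera adjusted p = 0.788), and sgk1 rose from 6.96 ± 0.273 to 37.9 ± 11.9 FPKM. Without control replicate 1, 1 of the 3 calls held. Of 6 genes of the insulin and growth hormone axis 2 rose and 2 fell, with 6 passing when adjusted over the list alone (camera adjusted p = 0.168), and the growth factor gene igf1, 1 of 2 entries, fell from 41.7 ± 8.30 to 8.18 ± 3.63 FPKM. Without control replicate 1, 2 of these 4 calls held. Of 5 oxidative phosphorylation genes 2 rose and 1 fell, with 5 passing when adjusted over the list alone (camera adjusted p = 0.23). The fall, of NDUFB4, lost its call without each of the 6 libraries (limma-voom adjusted p up to 0.238), and the rise of Ndufaf4 without control replicate 1 or heat stress replicate 2 (up to 0.0569). Of 3 antioxidant genes NFE2L2 and TXNRD3 rose and TXNIP fell, with 3 passing when adjusted over the list alone (camera adjusted p = 0.786), but both rises were below 0 under TMM, neither past the test. The calls of TXNRD3 and TXNIP were lost without control replicate 1, heat stress replicate 2 or heat stress replicate 3, and also without control replicate 3 for TXNRD3 and control replicate 2 for TXNIP, with limma-voom adjusted p up to 0.0964 and 0.0797. The 3 entries matched as ribosomal proteins rose, with 3 passing when adjusted over the list alone (camera adjusted p = 0.784), but 2 of them, Rps6ka3 and RPS6KB2, are ribosomal protein S6 kinases, and both were below 0 under TMM, neither past the test. Both kinase calls held only without heat stress replicate 1 (limma-voom adjusted p up to 0.209 for Rps6ka3 and 0.187 for RPS6KB2), and the rpl5a call only without heat stress replicates 1 or 2 (up to 0.0868). Both iron and heme genes, ppox and alas1, rose, too few for a list test, and 1 was below 0 under TMM, not past the test. The ppox call was lost without control replicate 1 (limma-voom adjusted p = 0.0534), and the alas1 call without control replicates 1 or 2 or heat stress replicates 2 or 3 (up to 0.142). Markers of erythrocytes, exocrine pancreas, leukocytes and skeletal muscle matched 0 listed genes. Description patterns longer than the 8 characters kept could not match, so genes without a matching symbol could be missed. Of the 3 stroma entries, col1a1b fell, whereas vimp and Tagln2, which matched by the start of their symbols alone, rose (camera adjusted p = 0.786). Tagln2 lost its call without control replicate 1 (limma-voom adjusted p = 0.0753).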

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

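TMM, listed-footprint library sizes, copies counted once, adjustment over the listed genes alone and the list tests under every scaling over the listed genes and with copies counted once were chosen after seeing the data, as was limma-voom on recovered depths as the main test in place of the planned one; the other alternatives were planned. The tests that needed a count model in place of limma-voom were not run, nor were their size factors in that model; median-of-ratios factors were used in limma-voom. Full library totals were not used, so sizes without the 10 most abundant genes were taken over the listed genes.

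The 1008 genes (821 higher, 187 lower) became 354 (88 higher) with median of ratios, 356 (90 higher) with TMM, 469 (207 higher) with listed footprints and 414 (150 higher) without the 10 most abundant. TMM and median of ratios bring the median of the listed genes near 0 by construction (0.18 and 0.12), and the sizes from listed footprints leave it at 0.73, or 0.47 without the 10 most abundant. With at least 10 FPKM in 3 libraries 556 genes passed (459 higher, 97 lower) of fewer tested, and 542 (476 higher, 66 lower) passed an adjusted p of 0.01. Leaving out each library gave 534 to 981 genes, 416 to 844 higher and 71 to 137 lower, with fewer samples per fit. Replicate numbers did not pair the samples (correlations of deviations -0.05, -0.04 and 0.01), and the replicate block gave 1102 genes, 882 higher and 220 lower. Of the 9 lists past the threshold, 0 passed with an estimated correlation, and fry, which asks another question, passed 22, as the selection of changed genes favours. The authors' counts of 924 and 289 stayed within 1.5 times under FDR under 0.01.

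Log2 fold changes turned negative, with median of ratios and TMM in that order, for RPS6KB2 and Rps6ka3 (-0.30 and -0.24 for both), NFE2L2 (-0.38, -0.32), TXNRD3 (-0.24, -0.19), Ugt2a2 (-0.47, -0.42), fga (-0.084, -0.030), c7b (-0.12, -0.063), CEBPB (-0.23, -0.18), NFKBIA (-0.35, -0.29), FKBP5 (-0.38, -0.33), irs2-b (-0.50, -0.45) and hsp90ab1 (-0.22, -0.16). Without the 10 most abundant genes they turned for NFE2L2 (-0.024), Ugt2a2 (-0.12), NFKBIA (-0.0006), FKBP5 (-0.032) and irs2-b (-0.16). None of these passed the test. Of the other named genes, 36 lost the call under TMM and 36 under median of ratios with the sign kept, 30 under listed footprints and 32 without the 10 most abundant. Of the named genes, 70 passed with each library left out, 35 lost the call in at least 1 such fit and 0 turned. Depth limits genes with few footprints, of which 61 were not tested.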

Other observations

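All tests of explanations in this part were chosen after the results were seen, as were the genes in this paragraph and the next, which were not tested as groups. Of all 1152 tested genes 71.3% rose by limma-voom. Of 12 listed entries for collagen-modifying enzymes and collagen chaperones, 11 rose and 1, a copy of P4HA2, did not pass. Of the 11, hsp47 and SERPINH1 are chaperones that the heat shock list also holds. The lysyl hydroxylase gene plod3 rose from 6.76 ± 0.737 to 97.7 ± 11.8 FPKM (SD, n = 3), the prolyl hydroxylase gene P4HA1 from 1.12 ± 0.238 to 29.8 ± 2.42 FPKM and SERPINH1 from 10.7 ± 2.57 to 351 ± 14.7 FPKM. The collagen gene col1a1b fell from 64.7 ± 6.62 to 28.7 ± 1.59 FPKM, whereas COL8A2, in 1 of 2 entries, rose from 75.9 ± 10.9 to 613 ± 319 FPKM. The other COL8A2 entry was not tested, and Col18a1, at 1.83 ± 0.574 and 0.553 ± 0.451 FPKM, did not pass.

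Of 9 entries for serine/arginine-rich splicing factors, 3 rose, 5 fell and 1 did not pass by limma-voom. Without control replicate 1, 1 of the rises and 4 of the falls kept their calls. SRSF5, as 1 of its entries, fell from 12.7 ± 2.10 to 0.877 ± 1.04 FPKM (SD, n = 3), SRSF2 fell from 22.0 ± 2.21 to 6.11 ± 0.599 FPKM, and SRSF7 rose from 4.02 ± 2.65 to 26.8 ± 2.17 FPKM. Of 9 entries of the NF-kappa-B family and its inhibitors 8 rose, with Relb, 1 of 2 entries, going from 4.64 ± 0.499 to 47.7 ± 17.0 FPKM. All of these entries except those of Relb are also in the acute phase and inflammation list. However, the NFKBIA entry with the smallest p, 1 of 3, was at -0.29 on the log2 scale under TMM, not past the test. It need not be the only one, since the sign turned under TMM in 5 members of the acute phase and inflammation list, none past the test. Of the 8 NF-kappa-B calls, 4 held without control replicate 1 and 5 without control replicate 3. One entry without a symbol was listed although it had footprints in heat stress replicate 2 alone, 64 in all.

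Entries with one symbol, copies that are common in trout, moved the same way in 94.6% of 166 pairs in the authors' deposited table. A permutation test on the directions gave at most 77.7% in 10000 draws (permutation p = 0.0001, the smallest they can give), which argues against the surplus of rises as the cause. Reads shared between near-identical copies could give the same pattern. Among 41 pairs at least 4-fold apart in level, fold changes differed by more than 2 standard errors in 43.9%. This leaves shared reads open, because reads shared only in part still let fold changes differ. Common regulation of duplicated genes stays open as well. Each listed copy was selected as changed, so the share says nothing about copies whose partner did not change. Copies of 7 symbols moved opposite ways, among them Cd276, where one rose from 2.15 to 16.6 FPKM and the other fell from 5.43 to 0.570 FPKM.

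The entries hsp70 and hsp70b were each at 0 in a different control library. Their footprints in control replicates 1, 2 and 3 were 19, 0 and 47 for hsp70 and 101, 52 and 0 for hsp70b. Reads divided between near-identical copies could give this. Over the heat stress libraries, which were not picked for the zeros, the sum per depth had a CV of 18.8%, between the 2.7% and 29.4% of the entries, which leaves divided reads open. Fish that carry or use different copies stay open too, since both entries had at least 4629 footprints in every heat stress library and those libraries are not labelled as the same fish. The sum was 393-fold higher in heat stress.

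More listed genes rose than fell. The share of rises was 66.2% among the genes above the median of control mean FPKM (95% Wilson interval over genes, taken as independent, 62.3% to 69.8%), a split that favours falls. It was 73.4% without the chaperone, TRiC and ER folding lists (70.7% to 76.0%), which argues against genes near 0 in the controls or those lists as the whole cause. A scale set by a total of different makeup could also produce it. With TMM over the listed genes the median shifted by -1.48, but genes outside the selection were not analysed here, so this cannot be told apart from a response to heat. The 1008 genes past the limma-voom threshold compare with at most 2 in the other splits, with 1 of 10 splits reaching that number, the real one; 10 splits are too few for a share under 0.05, and the genes were selected on the real split, so splits that mix the groups were bound to call few.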
